A study of Danio rerio with 6 samples.

How the data were processed

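RNA was measured by sequencing in 6 libraries of cells sorted from the apex of the zebrafish ventricle, 3 from uninjured hearts and 3 from regenerating hearts 5 days after the apex was resected. Cells were sorted by fluorescence from a line that carries a Gata4:GFP reporter, per the labels. Groups and replicate numbers were taken from the sample titles. The labels do not say whether each library came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. The labels have a tag called batch, but its values name the condition itself and no processing batch.

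STAR 2.5.3a, RSEM 1.3.0, DESeq2 and R 3.3.3 with the GRCz10 genome build are named in the submitters' processing notes, which give no version for DESeq2. The authors deposited log2 values of FPKM (fragments scaled to transcript length and to the total of the library) for 25089 genes, per the file headers. The values themselves showed the offset: after undoing the log2, 100% of the deposited values lay within 0.001 of a grid of 0.01 FPKM, and the lowest was 0.1. An offset of 0.1 was therefore subtracted, and the result is called FPKM here. Most genes with a mean normalised count of 0 stayed above 0 after that, so the values still hold a floor. The deposited table also gives the authors' own log2 fold change, p-value and adjusted p for each gene, with a mean normalised count. Its 3585 genes with a mean normalised count of 0 are listed with a p-value of 1. The authors' adjusted p differed from a Benjamini-Hochberg adjustment over the other 21504 genes by at most 1.65e-06. Their fold changes are quoted here only as the authors' values.

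The design fixed before the data were examined assumed counts and named a count test, with limma on log2(value + 1) if the values were normalised. The file held FPKM, so limma was used. No count test was run. Genes were kept when their FPKM was above 1 in at least 3 libraries, which left 13363 genes. The log2(FPKM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and group as the only term. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes.

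FPKM is relative to each library's own total, and mitochondrially encoded transcripts took a different share of that total in the groups. The median log2 change over all tested genes was 0.50 in the fit as planned. A scaling by median ratios over the 8963 genes above 1 FPKM in all 6 libraries was therefore added after seeing the data, and it brought that median to 0.05. Counts are given for both fits. Levels, fold changes and gene list counts are from the scaled values unless the planned fit is named, and levels are called scaled FPKM. Upper-quartile and trimmed-mean scalings were also added after seeing the data.

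Before the data were examined, 16 gene lists and 12 marker lists of cell types and of the dissociation response were fixed. Each was tested with limma's camera on the scaled log2 values with a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. Where a symbol occurred on several rows, the row with the highest mean was taken for a list. Genes were named by a rule fixed at the same time. It names gata4, and the 6 largest rises and 6 largest falls among genes past the threshold of the planned fit that averaged at least 10 FPKM in one group, had no overlap between groups and carried a symbol that is not a placeholder. It also names up to 2 members of each gene list with the smallest p and one in the other direction, up to 4 for the sarcomere and cytoskeleton lists, and the 2 most abundant members of each marker list. The rule was written in CPM and applied in FPKM. Genes named outside it are said to be chosen afterwards, and 1 gene that the rule names is not reported here. By chance, 10% of genes have groups that do not overlap with 3 libraries against 3.

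Some symbols had been turned into dates in the deposited table. Of 20 such symbols, 19 were restored from a table of gene identifiers and symbols, in which 22323 of the 25089 identifiers were found. No coordinates are given, because the reference tables used here are of another genome build.

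Depth cannot be read from the file as counts. The authors' mean normalised counts sum to 3510300 over genes. Among genes of at least 500 nt with a mean normalised count of 0, the median product of FPKM and length in kilobases ran from 0.145 in uninjured replicate 1 to 0.208 in uninjured replicate 2. As such genes have no counts, this value is a floor left in the deposited values. If the floor is inversely proportional to depth, uninjured replicate 2 was the shallowest library and the range was 1.44-fold, but the file does not give counts to check this. Low genes are therefore less precise than abundant ones by an amount that is not known here.

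The fit and the list test were tested on simulated data for this comparison, with 13363 genes, 200 of them changed, over 10 runs. The fit recovered 4.2% of genes changed 2-fold and 56% of those changed 4-fold, and 5.83% of its calls were false. The list test found the changed set in 10 of 10 runs and called 0.625% of random sets at an unadjusted p of 0.05. That set held only genes raised 4-fold, and simulated genes varied independently. In the data the estimated correlation within a list reached 0.74, so the list test was not checked for correlated genes. Recovery also depends on how many genes change. In the data 1526 genes passed relative to the median gene, so the simulated rates need not hold. Alternatives covered the pseudocount, the filter, a replicate block, a stricter threshold, a 1.5-fold null, each library left out in turn, and erythrocyte and mitochondrial genes left out.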

Results

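Transcript levels were measured in 6 libraries of ventricular cells sorted with a Gata4:GFP reporter, in which green fluorescent protein follows regulatory sequence of the heart transcription factor gene gata4. Of these, 3 came from uninjured hearts and 3 from hearts that were regenerating 5 days after resection of the apex. The comparison asks which transcripts differ between regenerating and uninjured cardiomyocytes, with sarcomere and cytoskeleton genes as the subject named in the study's title. FPKM summed to between 422675 and 535337 per library. Between 11334 and 12241 genes exceeded 1 FPKM in the uninjured libraries, and between 13505 and 13763 in the regenerating ones. Counts per library are not known, so precision rests on the spread between libraries.

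The first principal component held 52.1% of the variance and separated the groups. Spearman correlations across genes were 0.803 to 0.827 between uninjured libraries, 0.876 to 0.915 between regenerating libraries and 0.712 to 0.770 between groups. Transcripts of the 13 mitochondrially encoded genes made up 34.5% ± 11.1 (SD, n = 3) of summed FPKM in uninjured libraries and 14.0% ± 4.36 (SD, n = 3) in regenerating ones. That difference had an exact permutation p of 0.1 (two-sided), the smallest that 3 libraries against 3 allow.

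**Figure D1:**
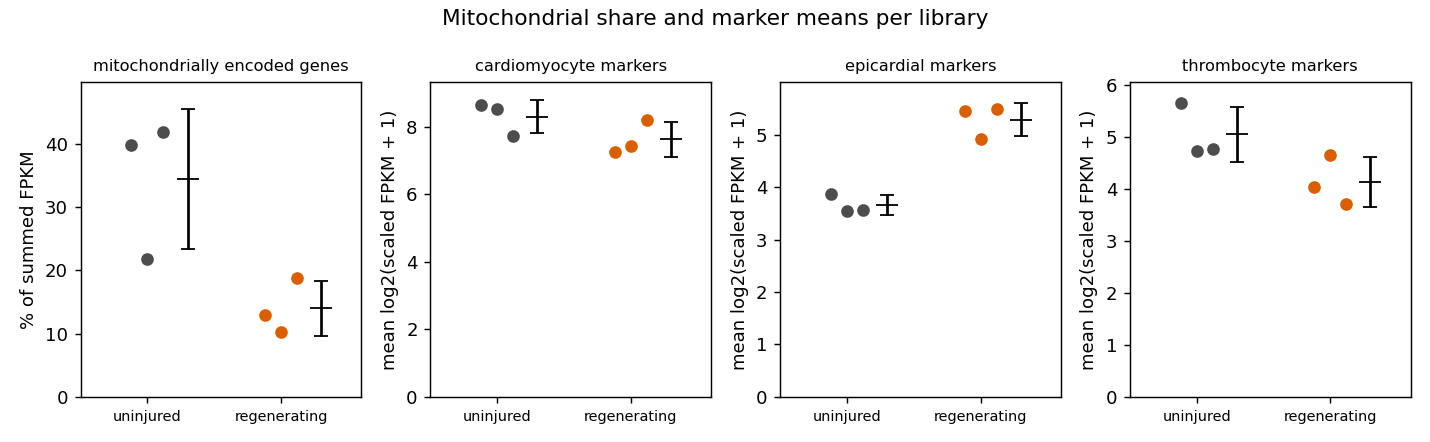
Share of summed FPKM from mitochondrially encoded genes (percent) and mean log2(scaled FPKM + 1) of cardiomyocyte, epicardial and thrombocyte markers, per library (points) with group mean and SD (bars, n = 3). The mitochondrial share lay between 10.3% and 18.8% in regenerating libraries and between 21.8% and 41.9% in uninjured ones.

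Relative to the median gene, 37 of 63 extracellular matrix genes and 33 of 67 mitosis and cytokinesis genes were higher in sorted cells of regenerating hearts, and 18 of 57 sarcomere genes were lower. With an estimated correlation the list tests had an adjusted p = 0.162 for the first list and the second, and an adjusted p = 0.356 for the sarcomere list. Of the 67 mitosis and cytokinesis genes, 32 exceeded 1 FPKM in no uninjured library. These passed the filter only through the regenerating libraries and could hardly come out lower. In the fit as planned, 3359 of 13363 genes changed, 3159 of them higher and 200 lower in regenerating cells (limma, adjusted p below 0.05). The median gene was higher by 0.50 on the log2 scale in that fit. Relative to the median gene, 1526 genes changed, 1001 higher and 525 lower, so that the share of higher genes went from 94.0% to 65.6%. All 1001 and 199 of the 525 also passed in the planned fit in the same direction. The authors' deposited table lists 2035 genes past an adjusted p of 0.05, 1041 higher and 994 lower, and 1293 of the 1526 genes were among them with the same direction. Relative to the median gene, 382 genes passed without regenerating replicate 1, 561 without replicate 2 and 645 without replicate 3 of that group. In the planned fit, 1157 passed without regenerating replicate 1, 1547 without regenerating replicate 3 and 2141 without uninjured replicate 3.

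By the naming rule, the largest rises began with midkine a (mdka, ENSDARG00000036036), a heparin-binding growth factor, which rose from 49.2 ± 5.12 to 1741 ± 238 scaled FPKM (SD, n = 3; log2 change 5.11, SE 0.23, limma adjusted p = 1.39e-05). The thioredoxin gene txn rose from 5.58 ± 1.73 to 148 ± 13.3 scaled FPKM. The leptin gene lepb rose from 0.388 ± 0.0263 to 36.2 ± 13.9 scaled FPKM, and the collagen gene col12a1b from 0.597 ± 0.140 to 36.0 ± 10.3. The uninjured values of lepb (589 nt) were close to what genes with a mean normalised count of 0 show at that length. The uninjured level and SD of lepb may therefore be a floor rather than measured expression, and its fold change is uncertain. The beta-globin row hbba1 (ENSDARG00000097238) rose by 4.74 (SE 0.99), but its near-identical copies may share reads and the authors' deposited table gives it an adjusted p of 0.323. The largest falls were in the nuclear receptor gene nr4a2b (log2 change -3.27, SE 0.38), TMEM269 (-3.21, SE 0.32), the keratin genes krt97 (-3.08, SE 0.31) and krt5 (-2.98, SE 0.35), nme2b.2 (-3.12, SE 0.60) and the claudin gene cldnb (-3.05, SE 0.48). All of these genes passed in both fits, and by construction their groups did not overlap. Reporter-related gata4 (ENSDARG00000098952) measured 16.3 ± 8.73 in uninjured and 9.52 ± 2.04 scaled FPKM in regenerating cells (SD, n = 3; log2 change -0.61, SE 0.36, limma adjusted p = 0.307), and its change was -0.06 without scaling (limma adjusted p = 0.946).

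Of 57 sarcomere genes tested, 18 fell, none rose and 39 did not pass (22 lower and 2 higher when adjusted over the list alone). The myosin heavy chain gene myh7ba (ENSDARG00000076075) fell from 163 ± 13.6 to 25.2 ± 5.29 scaled FPKM (SD, n = 3; log2 change -2.66, SE 0.24, limma adjusted p = 0.000471), and myh7bb from 55.3 ± 6.50 to 8.29 ± 1.68. The titin gene ttn.2 (ENSDARG00000028213), which encodes the elastic filament of the sarcomere, fell from 196 ± 25.6 to 38.7 ± 11.7 scaled FPKM, and the ventricular myosin gene vmhcl from 1287 ± 261 to 261 ± 56.8. Its relative vmhc, named after its value was seen, measured -0.75 (SE 0.37, limma adjusted p = 0.233) and -0.15 without scaling. These pairs of related genes (myh7ba and myh7bb, ttn.1 and ttn.2, vmhc and vmhcl) may share reads. That could not be checked here, so their separate levels are uncertain. The capping protein gene capza1a was higher in the planned fit and measured 0.72 (SE 0.24, limma adjusted p = 0.0902) relative to the median gene. At an unadjusted p below 0.05, limma gave 24 lower and 3 higher members. The planned fit had 11 lower and 4 higher members and a list median of -0.11. The list's median change was -0.70 relative to the median gene, with a camera adjusted p of 1.54e-09 and an adjusted p = 0.356 with an estimated correlation. Without regenerating replicate 1 the count of lower members was 9, and without regenerating replicate 2 it was 11.

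Among the 13 cardiomyocyte markers, of which 11 are also on the sarcomere list, ttn.2 and the myosin-binding gene mybpc3 fell and 11 did not pass. The gene mybpc3 was named after its value was seen. The regulatory myosin light chain gene myl7 measured 3185 ± 1119 in uninjured and 1846 ± 937 scaled FPKM in regenerating cells (SD, n = 3), a log2 change of -0.83 (SE 0.41, limma adjusted p = 0.227), and tpm4a one of -0.48 (SE 0.33). Without scaling tpm4a was above 0, at 0.13. The value of myl7 in regenerating replicate 3 (2907) was above that in uninjured replicate 3 (1914). The marker mean differed by -0.67 on the log2 scale (exact permutation p = 0.2, two-sided). The camera adjusted p of the marker list was 0.00102, with an adjusted p = 0.469 with an estimated correlation.

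**Figure D2:**
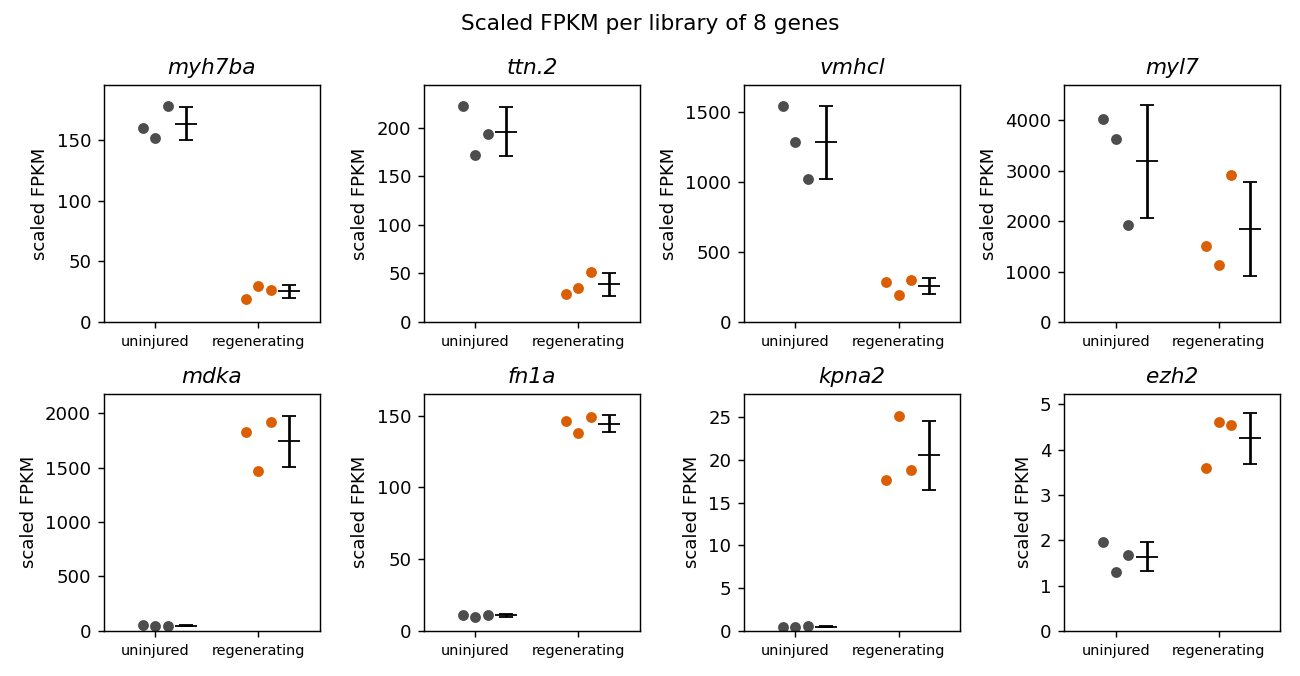
Scaled FPKM of 8 genes per library (points) with the group mean and SD (bars, n = 3), on linear axes from 0. The groups do not overlap for 7 of the genes, while myl7 ranges from 1132 to 2907 in regenerating and from 1914 to 4022 in uninjured libraries.

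Of 93 cytoskeleton and junction genes tested, 9 rose, 8 fell and 76 did not pass (14 higher and 9 lower when adjusted over the list alone). The tubulin genes tubb5 (ENSDARG00000037997) and tuba1a rose, tubb5 from 1.31 ± 1.09 to 40.8 ± 5.43 scaled FPKM (SD, n = 3; log2 change 4.29, SE 0.37, limma adjusted p = 0.000345) and tuba1a from 2.26 ± 1.43 to 23.7 ± 9.91. The non-muscle myosin light chain gene myl12.2 (1.43, SE 0.27) and the lamin A gene lmna (1.31, SE 0.27) also rose. The ankyrin gene ank2b, which anchors membrane proteins to spectrin, fell by 2.32 (SE 0.28). Tubulins have near-identical paralogs, so tubb5 and tuba1a may share reads with others. In the planned fit 29 members were higher and 4 lower. The list's median change was 0.09, camera's direction was down (adjusted p = 0.840, and adjusted p = 0.928 with an estimated correlation) and fry's was up. The higher members numbered 14 without uninjured replicate 1, 3 without regenerating replicate 1, 5 without regenerating replicate 2 and 4 without regenerating replicate 3. The lower members numbered 5 without uninjured replicate 3, 3 without regenerating replicate 1 or 2, and 5 without regenerating replicate 3.

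Of 63 extracellular matrix genes tested, 37 rose, 1 fell and 25 did not pass (44 higher and 3 lower when adjusted over the list alone; 45 higher and none lower in the planned fit). The fibronectin gene fn1a, a matrix protein of wound healing, rose from 10.7 ± 0.733 to 144 ± 6.002 scaled FPKM (SD, n = 3; log2 change 3.63, SE 0.21, limma adjusted p = 4.66e-05). The median change of the list was 1.25, with a camera adjusted p of 1.40e-14 and an adjusted p = 0.162 with an estimated correlation. Without regenerating replicate 1, 24 members were higher. Of 55 invasion and migration genes tested, 15 rose and 1 fell (16 higher and 2 lower when adjusted over the list alone; 24 higher and none lower in the planned fit). The membrane-bound matrix metalloproteinase gene mmp14b rose from 5.90 ± 2.16 to 30.7 ± 4.80 scaled FPKM, and the galectin gene lgals2a from 46.1 ± 5.74 to 189 ± 19.8. The list's camera adjusted p was 0.00129, with an adjusted p = 0.162 with an estimated correlation. Its higher members numbered 7 without regenerating replicate 1 and 8 without regenerating replicate 3.

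Markers of other cell types moved with these groups. Of 20 epicardial markers tested, 13 rose and 7 did not pass (15 higher when adjusted over the list alone; 17 higher in the planned fit), with a median change of 1.94 and the abundant keratin gene krt8 going from 299 ± 25.3 to 979 ± 172 scaled FPKM (SD, n = 3). Its other most abundant member, anxa1a, measured 469 ± 130 and 563 ± 211. The list's camera adjusted p was 5.64e-11, with an adjusted p = 0.180 with an estimated correlation. Of 23 fibroblast markers tested, 14 rose and 1 fell (17 higher and 2 lower when adjusted over the list alone; 17 higher and 1 lower in the planned fit), with a median change of 1.68 (camera adjusted p = 2.63e-08, and adjusted p = 0.218 with an estimated correlation). Of these 23 genes, 12 are on another list too. The most abundant were fn1b (log2 change 2.01, SE 0.30) and tnfaip6 (-0.24, SE 0.42, limma adjusted p = 0.764, and 0.38 without scaling). Of 32 endothelial and endocardial markers tested, 10 rose (13 when adjusted over the list alone; 19 in the planned fit), among them fabp11a (2.77, SE 0.36) and klf2a (1.02, SE 0.27). The camera adjusted p of that list was 4.63e-05, with an adjusted p = 0.453 with an estimated correlation. Its higher members numbered 5 without uninjured replicate 3, 2 without regenerating replicate 1 and 3 without regenerating replicate 2.

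Of 13 thrombocyte markers, which belong to the nucleated platelet-like cells of fish, 3 fell and 1 rose (10 lower and 1 higher when adjusted over the list alone). The riser was fn1b, which the fibroblast list also holds, and apln fell from 284 ± 140 to 99.4 ± 43.3 scaled FPKM (SD, n = 3) relative to the median gene but did not pass in the planned fit (limma adjusted p = 0.123). The planned fit had 2 lower members, 1 higher and a list median of -0.57. The list's median change was -1.17 relative to the median gene (camera adjusted p = 0.000117, and adjusted p = 0.453 with an estimated correlation). Of 18 smooth muscle and pericyte markers, 5 fell and 2 rose (8 lower and 2 higher when adjusted over the list alone). Smooth muscle actin gene acta2 fell from 274 ± 32.6 to 106 ± 22.1 scaled FPKM relative to the median gene (limma adjusted p = 0.0771 in the planned fit), while rgs5b rose by 2.31 (SE 0.32). The list's camera adjusted p was 1.24e-05, with an adjusted p = 0.304 with an estimated correlation, and its lower members numbered 3 without regenerating replicate 1.

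Blood cell markers were mixed. Of 28 macrophage and leukocyte markers, 7 rose (10 when adjusted over the list alone; 11 in the planned fit; camera adjusted p = 0.00389, and adjusted p = 0.515 with an estimated correlation). Its most abundant members, the antigen-presentation genes cd74a (-0.57, SE 0.42) and cd74b (-0.57, SE 0.45), did not pass in limma and were above 0, at 0.03 and 0.02, without scaling. The higher members numbered 2 without regenerating replicate 1 and 3 without regenerating replicate 2 or 3. Of 10 neutrophil markers 2 rose, and of 7 lymphocyte markers 1 rose (2 and 1 when adjusted over the list alone; 2 and 2 in the planned fit). The most abundant were srgn (-0.57, SE 0.40, and 0.04 without scaling) and nccrp1 (0.14, SE 0.46) for neutrophils, and dusp2, which rose by 1.41 (SE 0.38), and il2rga (-1.16, SE 0.57) for lymphocytes. The dissociation response list also holds dusp2. Both neutrophil risers, adam8a and mmp9, were named after their values were seen and are also on the invasion and migration list. Of 15 erythrocyte markers 4 rose (6 when adjusted over the list alone; 8 in the planned fit), and the most abundant, hbba1 (ENSDARG00000089087; 3.35, SE 1.18) and hbaa1 (3.66, SE 1.103), did not pass relative to the median gene but did in the planned fit. Camera adjusted p-values were 0.180, 0.840 and 0.0598 for the neutrophil, lymphocyte and erythrocyte lists, and 0.453, 0.883 and 0.642 as adjusted p with an estimated correlation. For lymphocytes the median (-0.06) and camera pointed down and fry up.

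Of 7 neural and Schwann cell markers 1 rose, also when adjusted over the list alone: the RNA-binding gene elavl4 (1.53, SE 0.25). The gene mbpa measured -0.46 (SE 0.26), and the camera adjusted p of the list was 0.748. Of 27 genes of the dissociation response, 5 rose and 1 fell (6 and 1 when adjusted over the list alone), and its most abundant members, the immediate early genes fosab (-0.38, SE 0.26, and 0.24 without scaling) and btg2 (-0.64, SE 0.27), did not pass. Its camera adjusted p was 0.748, and its higher members numbered 2 without uninjured replicate 2 or 3, 0 without regenerating replicate 1 and 1 without regenerating replicate 3. With an estimated correlation both lists had an adjusted p = 0.883.

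**Figure D3:**
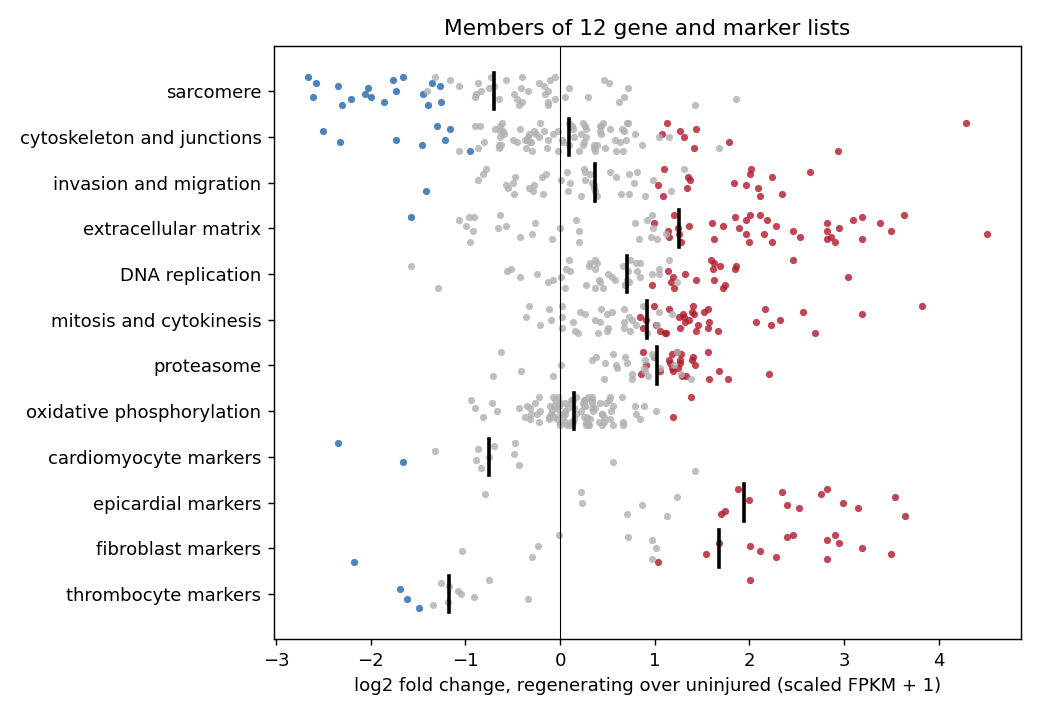
Log2 fold change of regenerating over uninjured for each tested member of 12 lists, on the log2(scaled FPKM + 1) scale (red, higher and blue, lower at an adjusted p below 0.05; grey, not past; black bar, list median). Medians run from -1.17 for thrombocyte markers to 1.94 for epicardial markers.

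Of 67 mitosis and cytokinesis genes tested, 33 rose, none fell and 34 did not pass (43 higher when adjusted over the list alone; 48 higher in the planned fit). The nuclear import gene kpna2 rose from 0.505 ± 0.0516 to 20.6 ± 4.05 scaled FPKM (SD, n = 3; log2 change 3.83, SE 0.26, limma adjusted p = 0.000108), and ube2c, which marks mitotic proteins for degradation, from 0.842 ± 1.09 to 14.2 ± 1.18. Of 60 DNA replication genes tested, 18 rose and none fell (29 higher and 2 lower when adjusted over the list alone; 36 higher and none lower in the planned fit). At an unadjusted p below 0.05, limma gave 44 higher and 0 lower mitosis genes and 30 higher and 2 lower replication genes. They included tyms, which makes thymidylate, at 2.01 ± 2.07 and 19.8 ± 0.881 scaled FPKM, and the ribonucleotide reductase gene rrm2 (2.46, SE 0.34). The authors' deposited table gives an adjusted p of 0.0954 for ube2c and 0.0923 for tyms, so neither passes there, while kpna2 (5.23e-20) and rrm2 (1.54e-11) do. The values of ube2c in uninjured replicates 1 and 2 and of tyms in uninjured replicate 2 were close to those of genes with a mean normalised count of 0. Their fold changes are therefore uncertain. Camera adjusted p-values were 1.24e-14 and 8.17e-08, with an adjusted p = 0.162 for the first list and adjusted p = 0.218 for the second with an estimated correlation. Without regenerating replicate 1, 2 or 3, 4, 3 and 3 mitosis genes and 1, 1 and 2 replication genes were higher. In those fits only 33, 33 and 31 mitosis genes and 38, 39 and 39 replication genes passed the filter. Of the members tested with all libraries, 32 mitosis and 20 replication genes exceeded 1 FPKM in no uninjured library. These passed the filter only through the regenerating libraries and could hardly come out lower. The counts of higher members and the p-values of both lists lean on them.

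Of 52 proteasome genes tested, 25 rose and none fell (38 higher when adjusted over the list alone; 44 higher in the planned fit). The core subunit gene psmb1 rose from 14.1 ± 2.01 to 43.5 ± 1.41 scaled FPKM (SD, n = 3), and the activator gene psme1 from 32.2 ± 6.87 to 106 ± 27.6. The median change was 1.02 (camera adjusted p = 4.65e-12, and adjusted p = 0.179 with an estimated correlation). The higher members numbered 10 without uninjured replicate 2, 15 without uninjured replicate 3, and 2, 6 and 10 without regenerating replicates 1, 2 and 3. Of 81 regeneration and stress signalling genes, 18 rose and 3 fell (22 higher and 8 lower when adjusted over the list alone). Besides mdka and lepb, the neuregulin receptor gene erbb3a was named and fell from 10.4 ± 4.27 to 2.30 ± 0.509 scaled FPKM. The list's camera adjusted p was 0.320, with an adjusted p = 0.642 with an estimated correlation, and its higher members numbered 7 without regenerating replicate 1 and 11 without regenerating replicate 2.

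Of 33 cardiac transcription factor genes, 2 rose and 4 fell (3 higher and 5 lower when adjusted over the list alone). The Notch-related repressor gene hey2 fell from 12.12 ± 6.75 to 1.04 ± 0.892 scaled FPKM (SD, n = 3), while irx5a (1.67, SE 0.32) and nr2f1a (1.44, SE 0.29) rose. Of 49 calcium handling and ion channel genes, 7 fell and 4 rose (9 lower and 6 higher when adjusted over the list alone), among them the calcium release channel gene ryr1b (-2.07, SE 0.28) and the rising channel-binding genes fkbp1ab (2.11, SE 0.27) and fkbp1aa (1.54, SE 0.30). Camera adjusted p-values were 0.107 and 0.00292, with an adjusted p = 0.304 and an adjusted p = 0.453 with an estimated correlation. The lower calcium genes numbered 2 without regenerating replicate 1 and 4 without regenerating replicate 2. Of 44 genes of Polycomb complexes and H3K27 methylation, a histone mark of repressed promoters, 3 rose and 1 fell (none when adjusted over the list alone). The methyltransferase gene ezh2 rose from 1.64 ± 0.326 to 4.25 ± 0.559 scaled FPKM (log2 change 0.99, SE 0.26, limma adjusted p = 0.0395), and the histone gene h3f3b.1 from 33.3 ± 15.09 to 71.9 ± 10.9. In the authors' deposited table ezh2 passes with an adjusted p of 0.00612 and h3f3b.1 does not (0.0754). The demethylase gene kdm6ba, named after its value was seen, fell by 1.04 (SE 0.27, limma adjusted p = 0.0357) but did not pass in the planned fit (adjusted p = 0.387). For this list the median was 0.09, camera's direction was down (adjusted p = 0.748, and adjusted p = 0.883 with an estimated correlation) and fry's was up.

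Most energy metabolism genes did not pass. Of 54 fatty acid oxidation genes, 3 rose and 4 fell (3 and 5 when adjusted over the list alone). The lipid-binding gene fabp11a and the lipase inhibitor gene angptl4 (2.15, SE 0.35) rose, while cpt1b, which admits fatty acids to mitochondria, fell from 20.1 ± 3.004 to 4.64 ± 1.28 scaled FPKM (SD, n = 3). Of 45 glycolysis genes 3 rose (2 when adjusted over the list alone; 9 in the planned fit), among them gapdhs (0.98, SE 0.22) and pgam1a (1.25, SE 0.29). Of 95 nuclear oxidative phosphorylation genes 2 rose (1 when adjusted over the list alone and 14 in the planned fit), cox6a1 (1.38, SE 0.23) and cox7a2a (1.19, SE 0.33). In the authors' deposited table cox6a1 passes with an adjusted p of 0.0149 and cox7a2a does not (0.0958). None of 33 citric acid cycle genes and none of 81 cytosolic ribosomal protein genes passed in limma relative to the median gene, also when adjusted over the list alone. At an unadjusted p below 0.05, limma gave 1 higher and 1 lower citric acid cycle gene and 3 higher and 2 lower ribosomal protein genes. In the planned fit 1 and 3 of them were higher, and suclg2 measured 0.77 (SE 0.32), rplp2l 0.71 (SE 0.23) and rps12 0.55 (SE 0.23) relative to the median gene. Camera adjusted p-values for the fatty acid, glycolysis, oxidative phosphorylation, citric acid cycle and ribosomal lists were 0.175, 0.389, 0.357, 0.320 and 0.240. With an estimated correlation the adjusted p was 0.720 for the fatty acid list and 0.883 for the other 4. The split of higher and lower members in the planned fit was 7 higher and 2 lower for calcium handling, 6 and 2 for cardiac transcription factors, 8 and 2 for fatty acid oxidation, 7 and 0 for Polycomb genes, 28 and 1 for regeneration signalling, 8 and 0 for the dissociation response, 2 and 3 for smooth muscle and 1 and 1 for cardiomyocyte markers. All 14 lists past camera's threshold lost it with an estimated correlation, and 10 lists passed in fry. Those were extracellular matrix, invasion and migration, mitosis, DNA replication, proteasome, regeneration signalling, epicardial, fibroblast, smooth muscle and neutrophil. Correlation alone does not account for the loss in camera. The invasion and migration list lost it although its estimated correlation was -0.01, below the preset 0.01. With these 6 libraries, camera's smallest adjusted p in that setting was 0.162 over the 28 lists. A failure there therefore does not decide against a list. The sarcomere list did not pass in fry (fry adjusted p = 0.0620). Neither did the cardiomyocyte (fry adjusted p = 0.160), thrombocyte (fry adjusted p = 0.160) and endothelial (fry adjusted p = 0.0620) lists.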

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

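The median-ratio, upper-quartile and trimmed-mean scalings, and the absence of scaling as an alternative for values relative to the median gene, were chosen after seeing the data. In the planned fit, the 3359 changed genes (3159 higher, 200 lower) became 1526 (1001, 525) with median-ratio, 1497 (897, 600) with upper-quartile and 1629 (1136, 493) with trimmed-mean scaling. With erythrocyte and mitochondrial genes left out they were 1280 (793, 487), and without a filter on low values 2079 (1978, 101). An adjusted p of 0.01 left 1288 (1237, 51) and a 1.5-fold null 777 (746, 31). Leaving out a library gave 1157 to 3796 changed, 1072 to 3656 higher and 85 to 220 lower. Relative to the median gene, the 1526 changed genes (1001, 525) became 3359 (3159, 200) without scaling, 681 (479, 202) without a filter, 402 (294, 108) at an adjusted p of 0.01 and 292 (217, 75) against a 1.5-fold null. Leaving out a library gave 382 to 1594 changed, 249 to 1056 higher and 133 to 538 lower. In these fits none of the 1526 genes still tested changed sign. They were picked as past the threshold with the same libraries, so a change of sign was unlikely from the start.

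Replicate numbers do not pair the libraries: deviations from the group means correlated at -0.01, -0.00 and -0.06 for numbers 1, 2 and 3, and 0 of the 3 uninjured libraries correlated best with their own number. With a replicate block the planned fit gave 2135 genes (2026 higher, 109 lower).

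The 18 lower sarcomere genes were 9 without a filter and 11 without scaling, and 9 to 16 when a library was left out. The 9 higher cytoskeleton genes were 29 without scaling and 3 to 14 with a library left out, and the 8 lower ones were 4 without scaling, 4 without a filter and 3 to 7 with a library left out. Of 54 named genes past the threshold, none reversed under any alternative. Between 33 and 54 of those still tested stayed past it in each. Many of these genes were named for a small p or a large change in the same libraries, so the lack of reversals lends no support. Removal of the filter adds low genes to the adjustment. A library left out changes the samples and the genes that pass the filter, and counts both rose and fell. The cause of the changes was not tested. DESeq2, limma-voom and the normalisation choices inside a count fit were not run, because they need counts. Low genes are limited by a depth that is not known here.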

Other observations

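All lists and genes in this paragraph were chosen after their values were seen, so their counts and p-values are descriptive. Of 19 genes that fold proteins in the endoplasmic reticulum, 14 rose in regenerating cells and none fell, with a median log2 change of 1.47. The chaperone gene hspa5 ranged from 113 to 189 scaled FPKM in regenerating and from 44.2 to 58.9 in uninjured libraries, and calr3b rose by 2.10 (SE 0.32, limma adjusted p = 0.00418). Of 24 genes of epithelial cells picked in this way, 13 fell, with a median of -1.49. Among them was icn2 (-2.57, SE 0.31), while its relative icn, which was not picked, rose from 525 ± 146 to 1076 ± 227 scaled FPKM (SD, n = 3; log2 change 1.051, SE 0.29, limma adjusted p = 0.0449). The adhesion gene epcam ranged from 86.4 to 115 scaled FPKM in uninjured and from 6.53 to 22.0 in regenerating libraries. The largest fall on that list (-3.08) was that of krt97, which the naming rule also gave. Whether epithelial cells were among the sorted cells was not tested. Regenerating replicate 3 had myh6 at 346 scaled FPKM against 29.0 to 109 in the other 5 libraries, nppa at 266 against 32.5 to 122 and tnnc1b at 649 against 33.1 to 234. It also had the highest myl7 (2907), actc1a (1159) and cmlc1 (2080) of the regenerating libraries.

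All tests of the 3 patterns below were chosen after the result was seen. The first pattern is the fall of 18 sarcomere genes. If fewer cardiomyocytes had entered the sort, their genes would fall by one common amount, but with each library set to its mean of the 13 cardiomyocyte markers, 13 of the 57 members were still lower and 5 higher (adjusted over the list alone), which argues against a lower share as the whole cause. As 11 of those markers are sarcomere genes, the reference was also changed, and 13 to 16 members were still lower and 2 to 7 higher under 4 other references. With the 2 markers outside the list it was 16 lower and 2 higher. Those markers, nppa (0.56, SE 0.61) and tpm4a (-0.48, SE 0.33), moved in opposite directions. Their mean therefore corrects for little, and this reference cannot gauge the share of cardiomyocytes. Removing the trend on transcript length in each library moved fold changes by -0.18 to 0.70 and changed 323 calls, and all 18 members remained lower, although fold change and length had a Spearman rho of -0.44 across the 57 genes. Of the 18 genes, 11 were lower and past the threshold under each of the 4 scalings, so for the other 7 the call depends on scaling, and a response to injury in cardiomyocytes stays open. The sort on the reporter may also have collected different cardiomyocytes in each group. This design cannot tell that apart from such a response.

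The second pattern is the rise of epicardial and fibroblast markers. Of 43 tested markers, 69.8% were higher by more than 1 on the log2 scale, but that share restates the pattern, so cells of these types among the sorted cells and expression of these genes by cardiomyocytes cannot be told apart. In all 3 uninjured libraries, 17 of the 20 epicardial and 21 of the 23 fibroblast markers exceeded 1 FPKM, and the sort on the reporter would remove cells only where they lack the fluorescence. Of the 27 markers that rose, 26 were higher and past the threshold under each of the 4 scalings. This test could hardly have removed a rise, so it does not decide on scaling. Without scaling the median gene moved up by 0.50, and all 1001 higher genes passed there too. The median change over all genes was similar with median-ratio (0.05), upper-quartile (0.0003) and trimmed-mean (0.09) scaling.

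The third pattern is the fall of mitochondrially encoded transcripts, with a median log2 change of -1.64 over 13 genes and 12 of them past the threshold relative to the median gene, but 0 in the planned fit, where the median was -1.02. The mean of these genes minus that of the cardiomyocyte markers differed by -0.96 between groups, with a pooled SD of 0.76 within groups and overlap between them, so a lower share of cardiomyocytes cannot be told apart from other causes with so few libraries. If less mitochondrial material per cell lowered nuclear oxidative phosphorylation transcripts too, these would fall. Their median change was 0.15 with an SD of 0.41 over genes, which argues against a joint fall of both sets of transcripts. Mitochondrial content was not measured and nuclear transcripts need not follow it, so less material per cell is not decided by this test. Injury itself stays open as an untested explanation.

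With 6 libraries there are 10 splits of 3 against 3, too few for a share under 0.05. In the planned fit the real split gave 3359 genes and the highest other split 0, with 1 split as large, the real one included. Relative to the median gene the real split gave 1526 and the highest other 0, again with 1 split as large.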
